A study of Homo sapiens with 42 samples.

How the data were processed

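RNA was sequenced from 7 human acute lymphoblastic leukaemia cell lines, each left untreated or exposed to L-asparaginase at 1 IU/ml for 4 h. L-asparaginase is an enzyme drug that breaks down asparagine, and to a lesser degree glutamine, in the medium. The labels describe 3 independent experiments per line, which gave 42 libraries in 14 groups of 3. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with standard Illumina reagents. The deposited values are whole-number read counts per gene symbol, in 1 table per line, not normalized by the authors. The submitters' processing notes name the hg19 genome build. The aligner, the counting tool, the gene annotation and whether counting used the strand are not given in the sources used here, so a gene and an overlapping antisense gene are not told apart.

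Columns were matched to the labels by line and treatment. The columns of 697 carry the replicate numbers 1 to 3. Those of the other lines carry the letters A, B and C, which no label mentions, so each such column was taken as a replicate of its group and is named by its letter. All 7 tables were joined on the gene symbol, which gave 50648 genes. Between 26 and 28 symbols per table had been turned into calendar dates, as spreadsheet software does, and are not named here. Among them, 2 names occurred more than once in the tables of 697 and CEM and were left out; they held at most 0.000949% of any library. No table held a summary line such as unassigned reads. The deposited counts per library summed to between 15.07 and 77.14 M (mega counts), with a median of 40.28 M. At the median depth, 1 CPM (count-per-million) rests on about 40.28 counts, and values far below 1 CPM carry large counting error. Counts of replicates differed well beyond sampling noise, with a lowest chi-square of 15 per degree of freedom between 2 libraries of a group, so no library was taken as a copy of another.

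Each line was tested on its own 6 libraries with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes were kept by filterByExpr with a minimum count of 10, and treated and untreated libraries were compared with glmQLFit and glmQLFTest. P-values were adjusted over genes by Benjamini-Hochberg, and a gene was called changed at an adjusted p under 0.05. A second edgeR model over all 42 libraries, with 1 coefficient per group, gave the mean response of the 7 lines, the interaction of treatment with line, and each line's response minus the mean of the other lines. CPM values were scaled by the same TMM factors. Values on the log2 CPM scale of single libraries use a prior count of 2, and log2 fold changes use the default of edgeR. The fold changes of a line in the report come from its own model, and those inside statements on the mean or the interaction come from the joint model. The median log2 fold change over all tested genes lay between -0.03 and -0.002 in the 7 lines.

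Before the data were examined, 20 response lists, 5 lists of cell type markers, the tests, most alternatives and a rule for which genes to name were fixed. The rule named 12 stress genes in every line, the 12 largest rises and 12 largest falls of the mean response among genes tested in all 7 lines with 1 sign in each, and the 4 largest rises and falls of each line with no overlap between groups. It also named the 8 interaction genes with the widest range between lines, and up to 4 changed members of each list. All but the per-list part required an average of at least 1 on the log2 CPM scale, except for the stress genes. The measured members of a list were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The list of mitochondrially encoded transcripts had no measured member, which left 19 lists. Adjusted p-values of lists are over the 19 lists of a comparison, and calls of their members are given over all genes tested and adjusted over the list alone. A relation over the 7 lines was tested by an exact two-sided permutation test of 5040 orders.

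Whether the numbers or letters pair an untreated with a treated library was checked by correlating their deviations from their group means over genes with an average of at least 3 on the log2 CPM scale. Every pair exceeded 0.1 in SUPB15 (lowest 0.19), RS411 (0.11), REH (0.43), CEM (0.23) and DND41 (0.36), and there the pairing, which comes from the column names and these correlations, was taken to hold, although in RS411 the highest correlation between libraries of different pairs was 0.27. It was not in Nalm6 (lowest 0.06) or 697 (-0.08). Models with the replicate as a block are given for the 5 paired lines beside some results, and their counts of changed genes in the part on processing.

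In a test on simulated data with the real means and library sizes, the models of single lines found between 93.8% and 100% of genes changed 4-fold, between 13.4% (697) and 89.4% (CEM) of those changed 2-fold, and between 4.5% and 55.4% of those changed 1.5-fold. False calls made up 2.6% to 6.5% of their calls. The simulation gave all genes of a line the same dispersion and held no deviating library, so the real data may give worse rates. The mean over the lines found 98.5% of genes changed 1.5-fold in every line, with 3.4% false calls. For genes changed in 1 line, the interaction found 92.4% of 4-fold, 20.9% of 2-fold and 0% of 1.5-fold changes, and 10 of its 85 calls were false. The list test found the simulated change of cholesterol synthesis genes and also called 1 of the other lists.

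Alternatives fixed in advance were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate block, the joint model in place of single lines, other thresholds, counts summed per line, and leaving out each library or line. Chosen after seeing the data were the older trended dispersion of edgeR, the removal of smooth GC content and length trends (lowess span 0.3, with GC and length taken by symbol from GENCODE release 29), models without 5 untreated libraries that stood apart, and models without 3 L-asparaginase libraries that held transcripts of other cells. The 5 are Nalm6 A, SUPB15 A, RS411 A, 697 1 and DND41 A. The 3 are SUPB15 C, RS411 B and REH A. Lists of hypoxia-induced genes, snoRNA host genes and markers of brain, liver, skeletal muscle and gut were also added after seeing the data. Of the genes named by the rule, 3 are not reported here. Coordinates are not given, because no annotation of the hg19 build was used.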

Results

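Gene expression was measured by RNA sequencing in 7 human acute lymphoblastic leukaemia (ALL) cell lines. Nalm6, SUPB15, RS411, REH and 697 derive from B-cell precursor leukaemia, and CEM and DND41 from T-cell leukaemia. Each line had 3 untreated libraries and 3 libraries made after 4 h with L-asparaginase at 1 IU/ml, so that n = 3 per group in every comparison within a line. Total counts per library, in mega counts (M), ranged from 24.52 to 77.14 M in Nalm6, 24.12 to 70.66 in SUPB15, 26.69 to 55.09 in RS411, 15.07 to 56.61 in REH, 30.42 to 62.77 in 697, 22.68 to 71.52 in CEM and 33.47 to 51.18 in DND41. In CEM the treated libraries (50.81 to 71.52 M) were all deeper than the untreated ones (22.68 to 31.6 M). The 10 most abundant genes of a library took between 8.36% and 21.55% of its counts, the highest share in REH L-asparaginase A, the shallowest library, where CTD-2328D6.1 alone took 5.49%.

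The lines expressed the genes of their lineage. The median untreated level of the B-lineage markers was 263, 218, 113, 240 and 101 CPM (counts-per-million) in Nalm6, SUPB15, RS411, REH and 697, against 0.295 in CEM and 0.531 in DND41. The T-lineage markers had untreated medians of 131 CPM in CEM and 145 CPM in DND41, and at most 0.079 CPM elsewhere. Untreated medians of the myeloid and stromal markers stayed at or below 0.507 CPM and 0.27 CPM in every line, and those of the erythroid markers at or below 0.00562 CPM.

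Several libraries differed from the others of their group. The first untreated library of Nalm6, SUPB15, RS411, 697 and DND41 deviated from its group in a shared way, with a median correlation of 0.71 across genes between these 5 deviations (genes are not independent replicates). In these 5 libraries SNORD3A was lower by 4.38 log2 units on average and TSPO by 2.87, and EIF5B was higher by 1.20. RN7SK, RN7SL1, RN7SL2, RPPH1, RMRP and SNORD3A, 6 small noncoding RNAs chosen after their counts were seen, took 3.35% to 7.23% of the counts of these libraries, the lowest share of each group. The mean share was higher in treated than in untreated libraries in 6 lines, as in 697 (12.42% ± 0.85% against 7.77% ± 4.37%, SD) and RS411 (13.92% ± 2.25% against 9.51% ± 3.44%), and lower in DND41 (8.08% ± 2.5% against 9.05% ± 2.97%). Without the 5 libraries it was 9.98% in untreated 697 and 10.65% in untreated RS411. Because all 5 are untreated, counts of changed genes are also given without them. A further 3 libraries, all treated, held transcripts at 1 CPM or more that the other 5 libraries of the line lacked (3 counts or fewer in sum): 89 genes in SUPB15 C, led by SNAP25 at 25.6 CPM, 18 in REH A, led by PRSS12 at 4.51 CPM, and 3 in RS411 B, TRBC2 at 1.46 CPM being the highest. None of the other 39 libraries held such a gene at 1 CPM or more, though lower traces of genes of other lines were seen in some.

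The first comparison asked what L-asparaginase did on average over the 7 lines. The genes ranked here were tested in all 7 lines, with 1 sign in every line and an average of at least 1 on the log2 CPM scale. The largest rise among them was that of INHBE, an activin subunit, with a mean log2 fold change of 3.08 ± 0.20 (SE), or 8.44-fold (adjusted p = 1.1e-14). The glycine transporter SLC6A9 rose 6.42-fold (2.68 ± 0.14) and the cystine transporter SLC7A11 4.41-fold (2.14 ± 0.13). SESN2, which restrains mTORC1 when amino acids are scarce, rose 6.01-fold (2.59 ± 0.17), and the transcription factor DDIT3 rose 4.86-fold (2.28 ± 0.078), each with the same sign in all 7 lines. The largest fall among them was that of PFKFB4, a regulator of glycolysis, at 8.99-fold lower (-3.17 ± 0.26, adjusted p = 3.9e-12), followed by that of INSIG1, a regulator of sterol synthesis (-2.06 ± 0.11).

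The other 7 of the 12 largest rises were TREML2 (6.36-fold), TRIB3 (5.16-fold), the pseudogene ROCK1P1 (4.18-fold), LRRC2 (3.42-fold), JDP2 (3.29-fold), ARRDC3 (3.27-fold) and ZNF425 (3.17-fold). Reads of a pseudogene and of its parent gene were not told apart. Other falls were ID2 (3.28-fold lower), SLC12A7 (3.26-fold), the splicing factor SRSF5 (3.03-fold), the pseudogene GTF2IP4 (2.97-fold), AC144652.1 (2.92-fold), the prolyl hydroxylase P4HA1 (2.84-fold), AC093818.1 (2.81-fold), GNAZ (2.79-fold) and the lymphoid polymerase DNTT (2.75-fold). Of the stress genes named in advance, CHAC1, which degrades glutathione, rose 4.27-fold (2.09 ± 0.16), PSAT1 3.30-fold (1.72 ± 0.18), and ASNS, the asparagine synthetase, 2.10-fold (1.07 ± 0.099, adjusted p = 5.2e-11). ATF3 and DDIT4 each rose by a log2 of 1.20 and PHGDH by 0.66 ± 0.075. The ATF4 transcript rose by 0.16 ± 0.052 (adjusted p = 0.012), and its call was lost with GC and length trends removed (0.13, adjusted p = 0.18) and without the line Nalm6, SUPB15 or CEM (0.13, 0.12 and 0.13). MYC had a mean of -0.04 ± 0.066 (adjusted p = 0.78).

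Of 20983 genes tested, 7762 (37%) changed on average, 3693 higher and 4069 lower. At least 2-fold, 363 were higher and 297 lower. Without the 5 untreated libraries that stood apart, 8708 changed, of which 6920 were among the 7762, and without the 3 treated libraries with transcripts of other cells, 7286 changed.

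Gene groups of the amino acid response moved together. Of 19 measured regulators of the integrated stress response, the pathway that shuts down general translation when amino acids run short, 16 rose and 1, EIF2AK4 (-0.50 ± 0.045), fell, counts that were the same adjusted over the list alone. Their median log2 fold change was 1.07, and STC2 (2.51 ± 0.37) stood beside SESN2, TRIB3 and DDIT3 as the strongest. Of 18 amino acid transporters 14 rose and 1, SLC38A5, fell (14 and 1 adjusted over the list alone), with SLC3A2 at 1.36 ± 0.11 and SLC1A4 at 0.90 ± 0.060. These were the 2 lists that camera called both with the preset correlation (adjusted p = 6e-11 and 4.5e-10) and with an estimated correlation (0.038 for each).

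Enzymes of amino acid synthesis and one-carbon metabolism had 13 of 23 members higher and 3 lower (13 and 4 adjusted over the list alone; adjusted p = 0.00058, 0.24 with an estimated correlation). The alanine transaminase GPT2 rose 4.33-fold (2.11 ± 0.20) and the serine pathway enzyme PSPH 2.41-fold (1.27 ± 0.092), and GOT2, ALDH18A1 and GLUL fell. The mean rise of BCAT1 (1.35 ± 0.32) rested on REH L-asparaginase A, and without that library it was 0.30 (adjusted p = 0.23). Of 20 cytosolic tRNA synthetases, which charge tRNAs with amino acids, 13 rose and 4 fell (14 and 4 adjusted over the list alone; adjusted p = 5.8e-07, 0.14 with an estimated correlation). WARS (1.24 ± 0.088), CARS (1.11 ± 0.069), MARS (0.95 ± 0.066) and GARS (0.88 ± 0.077) rose most, and DARS, KARS, QARS and RARS fell. Of 11 measured histone transcripts all 11 rose (11 adjusted over the list alone), with a median of 0.75, or 0.66 without the 5 untreated libraries (adjusted p = 6e-10, 0.09 with an estimated correlation for all libraries). Histone transcripts in general mostly lack a poly(A) tail, but whether these 11 do was not examined. HIST1H2BJ led them with 1.55 ± 0.16, followed by HIST2H2AA3 with 1.29 ± 0.13. In Nalm6 alone none of the 11 passed and the list did not (median -0.02, adjusted p = 0.88, 0.96 with an estimated correlation), although the mean share of the 6 small noncoding RNAs was 14.15% in treated and 10.26% in untreated libraries. In 697 none of the 11 passed, with a median of 0.59 (adjusted p = 0.0071, 0.39 with an estimated correlation).

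Of 24 cholesterol synthesis genes 18 fell and none rose (19 adjusted over the list alone; median -0.53, adjusted p = 6e-11, 0.12 with an estimated correlation), HMGCS1 by -1.30 ± 0.097 and IDI1 by -1.17 ± 0.068. Of 23 glycolysis genes 19 fell (19 adjusted over the list alone), among them PFKP (-1.16 ± 0.066), PFKM (-1.05 ± 0.073), HK1 (-1.0 ± 0.087) and LDHA (-0.91 ± 0.11), and the glucose transporter SLC2A3 rose by 0.72 ± 0.081 (median -0.57, adjusted p = 4.5e-08, 0.14 with an estimated correlation). Of 17 heat shock proteins 11 fell and none rose (12 adjusted over the list alone; median -0.42, adjusted p = 6.3e-05, 0.14 with an estimated correlation), led by HSPA8 at -1.02 ± 0.089. DNA replication genes had 16 of 28 members lower and 2, MCM6 and MCM7, higher (17 and 2 adjusted over the list alone; adjusted p = 3.6e-06, 0.14 with an estimated correlation). CCNE1 fell by -0.92 ± 0.068 and CCNE2 by -0.71 ± 0.067. Interferon-stimulated genes had 11 of 22 lower and 1, DDX58, higher (12 and 1 adjusted over the list alone; adjusted p = 0.0025, 0.13 with an estimated correlation), with STAT2 at -1.18 ± 0.067. Of 78 ribosomal proteins 34 fell and none rose (37 adjusted over the list alone; median -0.13, adjusted p = 0.00047, 0.63 with an estimated correlation), and without the 5 untreated libraries that stood apart 50 fell. In single lines with all libraries 36 of them fell in SUPB15 and 21 in DND41, and at most 2 in each of the others. Without the untreated library A of the line, 70 fell in SUPB15 and 28 in DND41. In 697 the list was higher than other genes (median 0.34, adjusted p = 0.0075, 0.54 with an estimated correlation). Its median there was 0.15 without untreated 1 (adjusted p = 0.018).

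Other groups went both ways. Mitosis genes had 8 members higher and 2 lower of 25 (adjusted p = 0.055, 0.63 with an estimated correlation), with CENPA at 0.72 ± 0.077, AURKA at 0.59 ± 0.053 and PLK1 at 0.54 ± 0.063, and the list passed with the replicate block in all 7 lines (0.03) and without the 5 libraries (0.0027). Immediate early genes had 11 of 22 lower and 2, JUN and KLF6, higher (adjusted p = 0.06, 0.63 with an estimated correlation), and passed with the block (0.045) and without the 5 libraries (0.0028). EGR3 (-2.27 ± 0.37), FOSB (-1.91 ± 0.23), NR4A1 (-1.63 ± 0.19) and EGR1 (-1.55 ± 0.20) fell most. Ribosome biogenesis genes, 14 higher and 10 lower of 34, with UTP20 at 0.70 ± 0.081, had an adjusted p of 0.23, 0.70 with an estimated correlation and 0.025 without the 5 libraries. Mitochondrial tRNA synthetases (8 higher, 5 lower of 17, adjusted p = 0.12), endoplasmic reticulum chaperones (7 and 5 of 20, 0.38), apoptosis regulators (7 and 6 of 22, 0.65), p53 targets (5 and 7 of 21, 0.37) and autophagy genes (7 and 3 of 24, 0.25) did not pass. Among them PARS2 rose by 1.07 ± 0.098, BAK1 by 0.77 ± 0.12 and TFEB by 0.69 ± 0.11, and ZMAT3 fell by -1.07 ± 0.10. In all, 11 of 19 lists passed, 12 without the 3 treated libraries and 14 without the 5 untreated ones. Of 100 splits of the libraries within lines, the real one included, 29 called as many lists, so chance was not excluded for the number of lists.

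**Figure D1:**
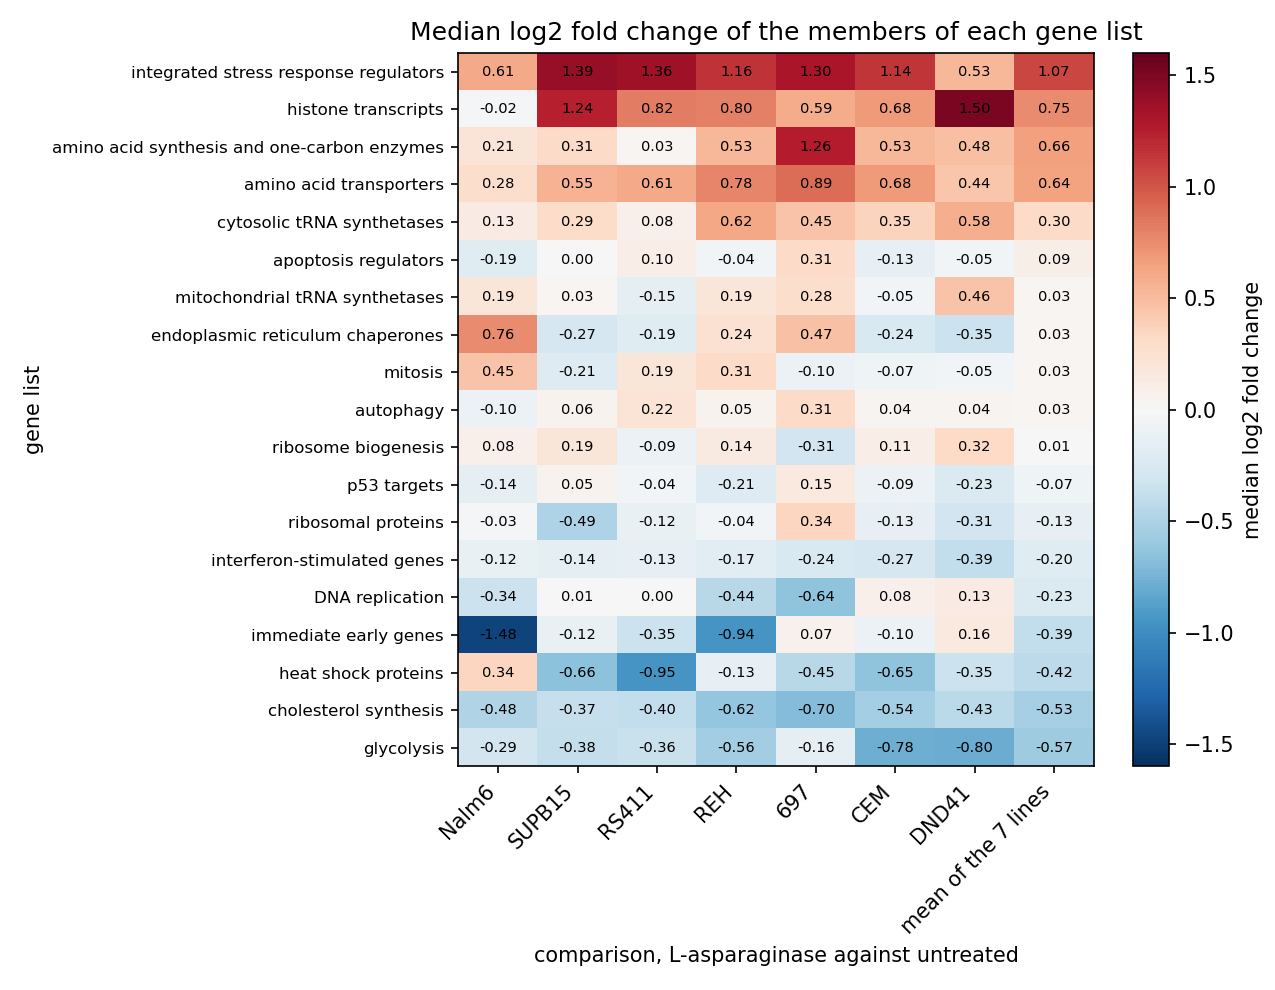
Median log2 fold change (L-asparaginase over untreated) of the measured members of 19 gene lists in each line and in the mean of the 7 lines; colour and printed number give the same value. Values of a line come from its own model. The stress response regulators lie between 0.53 and 1.39 in the 7 lines, and cholesterol synthesis lies between -0.70 and -0.37.

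Genes that changed in all 7 lines were sought in the 7 separate models. DDIT3, CEBPB, SLC7A11 and SLC6A9 were higher in every line, together with the mitochondrial one-carbon enzymes MTHFD2 and MTHFD1L, the serine enzyme PSPH, the transaminase GOT1 and the carboxykinase PCK2. INSIG1 and the isoprenoid enzyme IDI1 were lower in every line, as were P4HA1, GNAZ and TIMP2. In all, 31 genes were higher and 11 lower in each of the 7 lines, of 11722 tested in all of them, where 0.00082 and 0.00024 would come up if the lines were independent. In at least 5 lines, 508 genes were higher and 298 lower. The line 697 limited the number: without 697 untreated 1 it was 178, and without untreated 2 or 3 or L-asparaginase 1, 2 or 3 of 697 it was 6, 9, 3, 2 and 2. Without RS411 L-asparaginase C it was 25, without the 5 untreated libraries 301 (198 higher, 103 lower), and without the 3 treated libraries 28.

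Asparagine synthetase was compared in detail, since the study concerns resistance to a drug that removes asparagine. ASNS rose in CEM from 16.4 ± 1.25 (SD) to 92.2 ± 15.5 CPM, in 697 from 41.8 ± 5.31 to 203 ± 32.3 CPM and in REH from 69.2 ± 10.2 to 190 ± 46 CPM. The log2 fold changes were 2.49 ± 0.12 (SE; adjusted p = 2e-07), 2.28 ± 0.20 (0.0064) and 1.46 ± 0.17 (0.0003). In 697 the call was lost without L-asparaginase 2 (2.16, adjusted p = 0.054) or 3 (2.28, 0.07). ASNS did not pass in Nalm6 (0.58 ± 0.24, adjusted p = 0.11; 72.5 ± 31.4 to 109 ± 11.9 CPM), SUPB15 (0.27 ± 0.26, 0.48), RS411 (-0.04 ± 0.25, 0.93) or DND41 (0.53 ± 0.33, 0.26). It passed in Nalm6 without untreated B (1.00, adjusted p = 0.0024) and in DND41 without L-asparaginase A (0.84, 0.038). Untreated SUPB15, RS411 and DND41 had only 1.21 ± 0.26, 1.36 ± 0.166 and 1.76 ± 0.259 CPM of ASNS (SD), and untreated levels differed between the 7 lines (adjusted p = 1.7e-23).

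The response of ASNS differed between lines (interaction adjusted p = 2.3e-06). It exceeded the mean of the other lines by 1.64 in CEM (adjusted p = 0.0003) and 1.43 in 697 (0.00036), and fell short of it by -1.31 in RS411 (0.034). Over the 7 lines, untreated level and response had r = 0.62 (exact permutation p = 0.14, BH adjusted 0.17) and rho = 0.61 (exact permutation p = 0.17, BH adjusted 0.17), two-sided, with r and rho as the family. Without SUPB15 and RS411, the lines farthest from the median level, r was 0.28, and without the 5 untreated libraries 0.57.

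**Figure D2:**
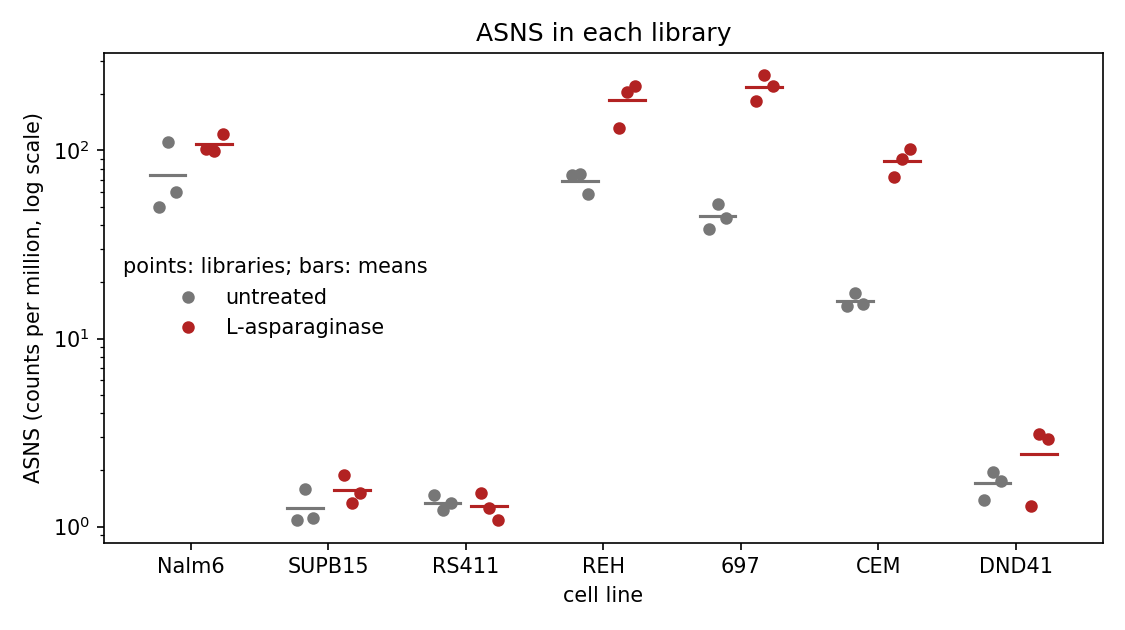
ASNS in counts-per-million (CPM, log axis) in each of the 42 libraries, by cell line and treatment; points are libraries and bars are group means. Treated libraries lie at 72.1 to 102 CPM in CEM, 184 to 251 in 697 and 131 to 221 in REH, above all untreated ones of their line. SUPB15, RS411 and DND41 stay near 1 to 3 CPM. The CPM values drawn here are scaled otherwise than those of single lines in the text, so the means differ somewhat.

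Each line was then compared on its own. In Nalm6, NR4A3 dropped 22.9-fold, from 15.6 ± 3.68 (SD) to 0.686 ± 0.13 CPM, CPN2 16.7-fold, EGR1 15.5-fold (-3.96 ± 0.45, SE) and the platelet glycoprotein gene GP5 10.7-fold. DDIT3 rose 5.68-fold (2.51 ± 0.14, adjusted p = 9e-06), INHBE 5.98-fold, the potassium channel KCNK3 5.76-fold and RP11-290D2.6 5.80-fold. SNORD3A rose 8.99-fold (adjusted p = 0.03). It is the gene most reduced in the untreated libraries that stood apart, and its call was lost without untreated C (2.99) or L-asparaginase A (3.45) or C (2.55). Of 20 immediate early genes 15 fell (15 adjusted over the list alone; median -1.48, adjusted p = 4.6e-08, 0.53 with an estimated correlation). Chaperones of the endoplasmic reticulum had 10 of 20 higher (13 adjusted over the list alone; adjusted p = 6.7e-06, 0.57 with an estimated correlation) and mitosis genes 10 of 25 (14 adjusted over the list alone; 6e-07, 0.57 with an estimated correlation). Of 14952 genes 3152 changed (1366 higher, 1786 lower). Without the untreated library A it was 3800, and without L-asparaginase A, B or C 1996, 1703 and 1708.

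In SUPB15, a line with the BCR-ABL1 fusion, INHBE rose 31.5-fold, from 2.16 ± 0.966 to 69.6 ± 8.69 CPM (SD), and CHAC1 16.5-fold, from 5.06 ± 2.33 to 84.8 ± 2.87 CPM. The matrix protein gene THBS1 rose 15.2-fold (3.93 ± 0.15, SE), SLC12A8 13.6-fold and DDIT3 10.3-fold (3.36 ± 0.15, adjusted p = 2.5e-05). The falls were led by RP11-1018N14.5 (7.79-fold lower), LINC00616 (6.68-fold), the thrombin receptor F2R (6.58-fold) and CEACAM6 (6.44-fold). Of 78 ribosomal proteins 36 fell (46 adjusted over the list alone; median -0.49, adjusted p = 1.2e-09, 0.54 with an estimated correlation), and 70 fell without the untreated library A. Of 11 histone transcripts 10 rose (11 adjusted over the list alone; median 1.24, adjusted p = 4.5e-08, 0.51 with an estimated correlation). Of 15121 genes 4001 changed (1982 higher, 2019 lower). Without the untreated library A it was 6445, without untreated C 2624, without L-asparaginase B 1769 and without L-asparaginase C, the library with SNAP25, 2267.

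In RS411, which carries a KMT2A-AFF1 fusion, heat shock transcripts fell: HSPA1A fell 16-fold, from 6.37 ± 2.75 to 0.398 ± 0.314 CPM (SD), and 14 of 16 heat shock genes were lower (14 adjusted over the list alone; median -0.95, adjusted p = 9.9e-11, 0.06 with an estimated correlation). INSIG1 fell 5.25-fold and HSPA8P1, a pseudogene of HSPA8, 4.10-fold. The C-type lectin CLEC17A rose 17.5-fold (4.13 ± 0.27, SE), STC2 13.3-fold, INHBE 11.2-fold and SESN2 9.54-fold (3.25 ± 0.14, adjusted p = 3.9e-05). Of 18 stress response regulators 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.36, 8.1e-11, 0.06 with an estimated correlation). Of 16345 genes 2171 changed (1286 higher, 885 lower). Without the untreated library A it was 4640, without untreated B or C 1179 and 1218, without L-asparaginase A or C 1021 and 392, and without L-asparaginase B, which held TRBC2, 501.

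In REH, which carries an ETV6-RUNX1 fusion, the early growth response genes fell most: EGR1 fell 47.1-fold, from 17.2 ± 5.51 to 0.448 ± 0.346 CPM (SD), EGR2 61.6-fold and EGR3 45.7-fold. MIR210HG, the host of a hypoxia-induced microRNA, fell 37.8-fold (-5.24 ± 0.53, SE). ALPK2 rose 30.4-fold, CLEC17A 19.2-fold, GDAP1L1 18.8-fold, each from a low untreated level, and DDIT4L rose 10.1-fold (3.34 ± 0.22, adjusted p = 1.2e-05). Of 28 DNA replication genes 19 fell (20 adjusted over the list alone; median -0.44, adjusted p = 5.6e-08, 0.40 with an estimated correlation), and 15 of 23 cholesterol genes fell (18 adjusted over the list alone; 1.3e-10, 0.28 with an estimated correlation). Amino acid transporters had 13 of 17 higher (14 adjusted over the list alone; 4.7e-08, 0.28 with an estimated correlation). Of 15549 genes 4224 changed (2103 higher, 2121 lower), and 6648 with the replicate block. Without untreated B it was 2615, and without L-asparaginase B or C 2468 and 2584.

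In 697, the pseudokinase gene TRIB3 rose 75.7-fold, from 0.751 ± 0.917 to 54.8 ± 9.85 CPM (SD), GDAP1L1 116-fold (6.86 ± 0.39, SE), COLGALT2 37.6-fold and the peptide gene SPX 18.9-fold. LINC00616 fell 87.1-fold (-6.45 ± 0.60), PFKFB4 16.7-fold, CTD-2651B20.6 10.6-fold and AHRR 8.91-fold. DDIT3 rose 2.97-fold (1.57 ± 0.22, adjusted p = 0.02), and CHAC1 did not pass (-0.09 ± 0.70, 0.95). The calls of TRIB3, DDIT3, PFKFB4, CTD-2651B20.6 and AHRR were lost without any 1 library other than untreated 1, with log2 values between 5.94 (TRIB3 in 697 without 697 untreated replicate 3) and 7.59 (without untreated 2) for TRIB3 and between 1.39 and 1.74 for DDIT3. That of LINC00616 in 697 was lost without 697 L-asparaginase replicate 1 (-6.47) or replicate 3 (-5.86). Of 23 synthesis and one-carbon enzymes 10 rose (12 adjusted over the list alone; median 1.26, adjusted p = 3.7e-10, 0.17 with an estimated correlation), and 5 of 28 DNA replication genes fell (15 adjusted over the list alone; median -0.64, 1.7e-10, 0.17 with an estimated correlation). Without untreated 1, 14 of these enzymes rose and 1 fell, and 20 of the DNA replication genes fell. Of 15306 genes 401 changed (255 higher, 146 lower), against 4170 in the joint model. In the model of 697 alone it was 3751 without untreated 1, without untreated 2 or 3 it was 23 and 59, and without L-asparaginase 1, 2 or 3 it was 23, 12 and 11.

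In CEM, MIR210HG fell 72.3-fold, PFKFB4 22.8-fold, from 72.8 ± 36.3 to 3.18 ± 0.708 CPM (SD), the adenylate kinase AK4 14-fold and the mitophagy gene BNIP3 12.2-fold, from 177 ± 94.6 to 14.5 ± 2.74 CPM. SLC6A9 rose 21.1-fold (4.40 ± 0.25, SE), the metallothionein MT1H 20.5-fold, ROCK1P1 17.4-fold and GPT2 15.7-fold (3.98 ± 0.15, adjusted p = 6.1e-08). SLC7A11 rose 12.5-fold (3.64 ± 0.21). Of 23 glycolysis genes 19 fell (19 adjusted over the list alone; median -0.78, adjusted p = 1e-08, 0.48 with an estimated correlation), and 14 of 17 heat shock genes fell (15 adjusted over the list alone; 1.9e-06, 0.49 with an estimated correlation). Transporters had 13 of 18 higher and 2 lower (15 and 2 adjusted over the list alone; 5.1e-07, 0.095 with an estimated correlation). MYC fell by -0.35 ± 0.094 (adjusted p = 0.011), a call lost without L-asparaginase C (-0.25, 0.065). Of 16080 genes 5974 changed (3073 higher, 2901 lower), against 2965 in the joint model.

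In DND41, histone transcripts rose most: HIST1H2BM 38.2-fold, from 4.93 ± 2.78 to 188 ± 29 CPM (SD), HIST1H4F 48.1-fold and HIST1H2AJ 17.1-fold, beside the matrix protease MMP9 at 23.7-fold (4.57 ± 0.40, SE). MIR210HG fell 54.6-fold, PFKFB4 16.5-fold, NR4A1 13.7-fold and the peptide hormone gene APLN 10.6-fold. DDIT3 rose 2.13-fold (1.09 ± 0.15, adjusted p = 0.0015), and CHAC1 was at 0.85 ± 0.29 (0.053), which passed with the replicate block (0.0012) and without untreated A (0.57, 0.04). Of 11 histone genes on the list 9 rose (9 adjusted over the list alone; median 1.5, adjusted p = 4.6e-06, 0.33 with an estimated correlation), and 21 of 78 ribosomal proteins fell (21 adjusted over the list alone; 3.4e-07, 0.33 with an estimated correlation). Of 14951 genes 4073 changed (2285 higher, 1788 lower). Without the untreated library A it was 5397, without untreated C 2608, and without L-asparaginase B or C 2195 and 1901.

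**Figure D3:**
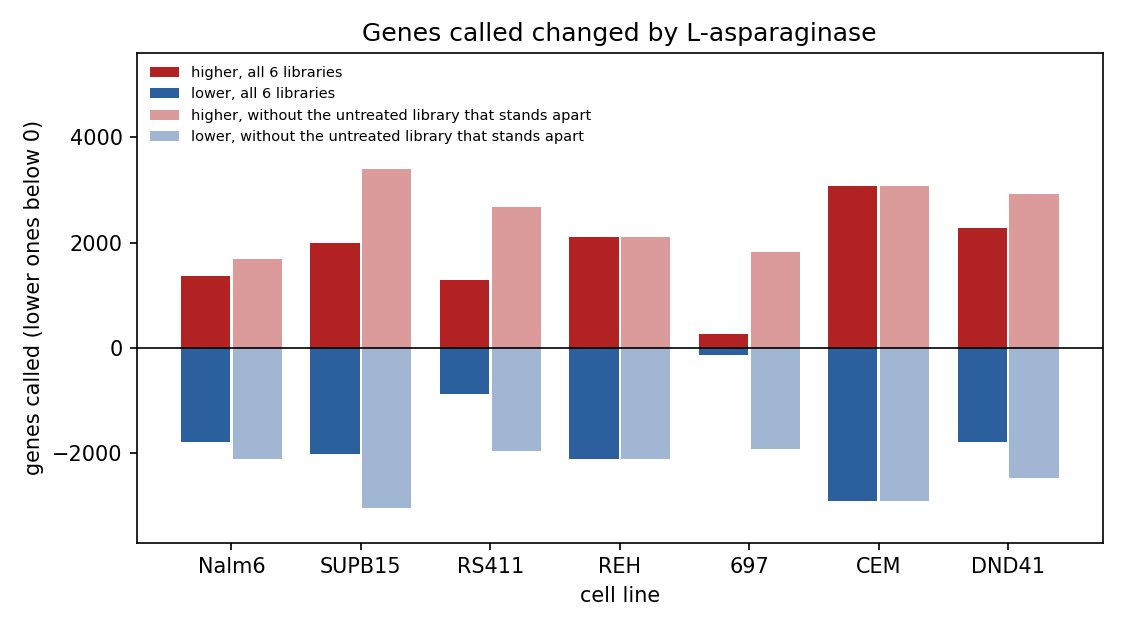
Number of genes called changed in each line, higher ones above 0 and lower ones below, with all 6 libraries (dark bars) and without the untreated library that stood apart (pale bars; REH and CEM had none). CEM has 3073 higher and 2901 lower genes, and 697 goes from 255 and 146 to 1822 and 1929 without untreated 1.

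Whether the lines differed in their response was tested by the interaction of treatment with line, which called 4435 of 20983 genes (21.1%), 7549 without the 5 untreated libraries and 3569 without the 3 treated ones. TRIB3 ranged from a log2 of 0.88 in Nalm6 to 6.29 in 697 (interaction adjusted p = 4.5e-06) and CHAC1 from -0.10 in 697 to 4.06 in SUPB15 (7.2e-05). DDIT3 ranged from 1.06 in DND41 to 3.38 in SUPB15 (1.4e-06). The death receptor FAS was at -3.18 in REH and 1.67 in 697 (6.1e-11), the chaperone HSPA5 at 1.16 in Nalm6 and -1.61 in DND41 (1.8e-06), and EGR1 at -5.60 in REH and 1.03 in SUPB15 (3.7e-07). WARS reached 3.16 in 697 against 0.60 to 1.42 elsewhere (4.6e-06). SLC3A2 (0.91), SESN2 (0.052) and PSPH (0.21) did not pass.

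The widest ranges between lines came from genes near 0 CPM in the lines that set the range, and 2 of the 8 are not reported here. NSG1, CNKSR2 and PTPRD owed theirs, 8.99 to 10.39 log2 units, to SUPB15 L-asparaginase C. SH2D1A (9.68) owed its range to RS411 L-asparaginase B, and CD34 (9.20) to 697 untreated 1 and to REH. WDR72 (9.28) was seen in the treated libraries of SUPB15, RS411 and REH at under 1 CPM.

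**Figure D4:**
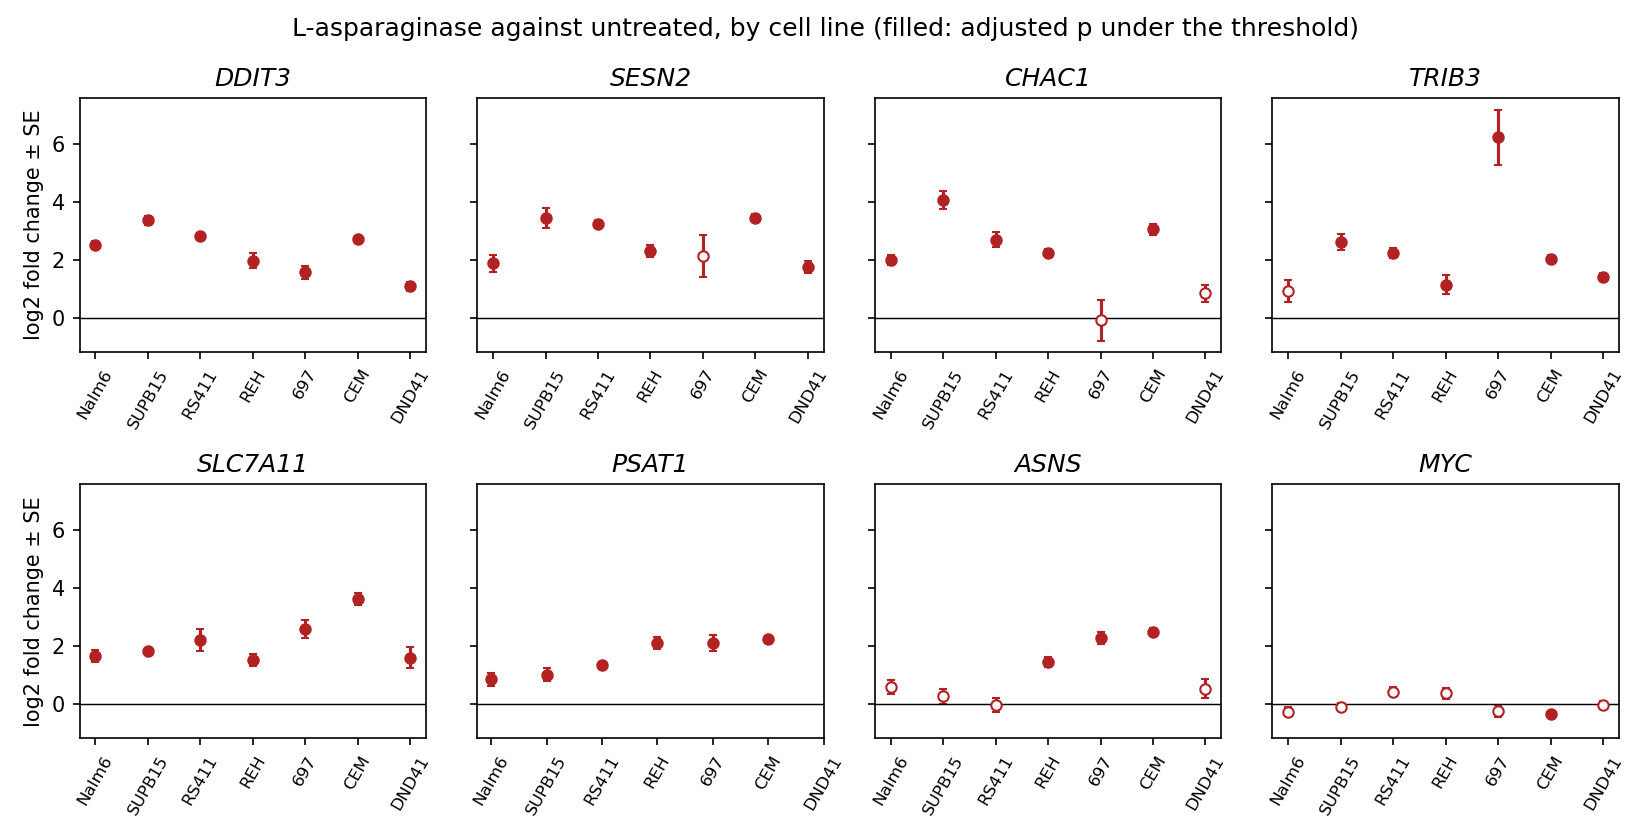
Log2 fold change (L-asparaginase over untreated) ± SE of 8 genes in each line's own model; filled points have an adjusted p under 0.05, and PSAT1 has no point in DND41, where it was not tested. DDIT3 is filled in all 7 lines, from 1.09 in DND41 to 3.36 in SUPB15, and ASNS in REH, 697 and CEM.

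The response of each line was also set against the mean of the other 6. In 697, TRIB3 exceeded it by 4.58 (adjusted p = 8e-07) and CHAC1 fell short by -2.56 (0.0004). In DND41, HIST1H2BM exceeded it by 4.78 (1.7e-10) and DDIT3 fell short by -1.43 (4.3e-05). In SUPB15, CHAC1 exceeded it by 2.30 (0.0029), DDIT3 by 1.29 (0.00035) and SLC12A8 by 2.84 (2.9e-05). In REH, EGR2 fell short by -5.37 (4e-05) and EGR1 by -4.73 (2.2e-05). EGR1 also fell short in Nalm6 (-2.86, 0.0057), ROCK1P1 exceeded the others in CEM (2.39, 0.0032), and of the genes named in RS411 only ASNS passed (-1.31, 0.034).

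The number of such genes was 1991 in 697 (952 higher, 1039 lower), 1275 in DND41 (665, 610), 669 in SUPB15 (397, 272), 561 in Nalm6 (163, 398), 504 in REH (183, 321), 244 in CEM (126, 118) and 234 in RS411 (135, 99). With the replicate block it was 1078 in SUPB15, 849 in REH, 443 in CEM and 498 in RS411. Without the 5 untreated libraries it was 1569 in Nalm6, 1589 in SUPB15, 1093 in RS411, 1274 in REH, 756 in CEM and 2560 in DND41. Without the 3 treated libraries it was 291 in SUPB15, 77 in RS411 and 298 in REH. Without 697 untreated 1 alone it was 1011 in Nalm6, 1208 in SUPB15, 582 in RS411 and 427 in CEM. Libraries of the line itself lowered the counts when left out. In 697 it was 1224 without L-asparaginase 2 and 1078 without 3, and in Nalm6 252 without untreated B and 296 and 272 without L-asparaginase B and C. In SUPB15 it was 381 and 333 without untreated B and C and 405 and 351 without L-asparaginase B and C, and in RS411 105, 95, 87 and 72 in the same order. In REH it was 284 and 255 without untreated B and C and 238 and 250 without L-asparaginase B and C, and in DND41 815, 740, 720 and 691. In CEM it was 159, 115 and 97 without untreated A, B and C and 131, 95 and 101 without L-asparaginase A, B and C.

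Across 8348 genes, which are not independent replicates, the responses of 2 lines correlated with a median r of 0.49 over 21 pairs. SUPB15 and RS411 were closest (0.78), followed by the T-cell lines CEM and DND41 (0.68), and 697 and DND41 were farthest apart (0.28). Without the 5 untreated libraries the median was 0.53, with SUPB15 and RS411 at 0.73, 697 and DND41 at 0.36 and SUPB15 and 697 farthest apart (0.34).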

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

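All tests of the 3 patterns weighed here (libraries that stood apart, ASNS, and transcripts seen in 1 library) were chosen only after the result was seen; the interaction tests and the splits were planned.

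The response to L-asparaginase differed between lines for 4435 genes in the interaction test, and this part lists the named results with such a difference. Against the mean of the other lines, 561 genes differed in Nalm6, 669 in SUPB15, 234 in RS411, 504 in REH, 1991 in 697, 244 in CEM and 1275 in DND41. Of 103 named genes with a mean response, 74 passed the interaction test, and for each the value given is the highest minus the lowest log2 fold change of the 7 lines. Among stress genes the range was 5.40 for TRIB3, 4.16 for CHAC1, 3.07 for STC2, 3.02 for ATF3, 2.53 for ASNS, 2.33 for DDIT3, 1.64 for PSAT1, 1.51 for PHGDH and 0.90 for ATF4. Among transporters, amino acid enzymes and tRNA synthetases it was 7.67 for BCAT1, 3.45 for GPT2, 3.19 for SLC6A9, 2.55 for WARS, 2.14 for SLC7A11, 1.31 for CARS, 1.18 for MARS, 1.16 for EARS2, 1.11 for WARS2 and 1.08 for SLC1A4. Among the other large rises of the mean response it was 3.38 for INHBE, 3.22 for TREML2, 3.19 for LRRC2, 2.85 for ROCK1P1, 2.37 for ARRDC3, 1.66 for JDP2 and 1.31 for ZNF425. Among the large falls it was 4.62 for SLC12A7, 4.27 for PFKFB4, 2.56 for ID2, 2.24 for AC093818.1, 1.64 for P4HA1, 1.63 for SRSF5, 1.45 for GNAZ and 1.32 for INSIG1. Among chaperones and heat shock proteins it was 2.77 for HSPA5, 2.72 for BAG3, 2.26 for HSPA8, 1.92 for HSP90B1, 1.88 for HERPUD1 and 1.29 for XBP1. Ribosomal protein, replication and mitosis genes spanned 1.83 (CCNE2), 1.65 (CCNE1), 1.46 (CDC6), 1.31 (RPL24), 1.22 (RPS25), 1.22 (CENPA), 1.09 (PLK1), 0.87 (AURKA) and 0.84 (GINS2). Genes of cell death, p53 and autophagy spanned 4.85 (FAS), 3.12 (BBC3), 2.59 (ZMAT3), 1.87 (TFEB), 1.35 (CCNG1) and 1.09 (DDB2). Immediate early and interferon genes spanned 6.73 (EGR3), 6.63 (EGR1), 4.63 (NR4A1), 3.88 (FOSB), 2.30 (IFIT1), 1.74 (IFIT3) and 1.21 (STAT2). Glycolysis and histone genes spanned 2.28 (HIST1H2BJ), 2.10 (HIST1H2AC), 2.09 (HIST2H2AA3), 1.86 (HK1), 1.6 (HIST1H2BK) and 1.41 (PFKM). The widest ranges were 10.39 for NSG1, 9.68 for SH2D1A, 9.28 for WDR72, 9.20 for CD34, 9.19 for CNKSR2 and 8.99 for PTPRD. The ranges of NSG1, CNKSR2 and PTPRD rested on SUPB15 L-asparaginase C, that of SH2D1A on RS411 L-asparaginase B, and that of BCAT1 on REH L-asparaginase A.

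Other splits of the libraries were counted for these results. Within every line, 100 splits were drawn, and chance can be excluded for the genes changed on average (7762, highest other 1119, 1 split as large). For the genes with the same direction in all lines (42, highest other 0, 1 split) the splits cannot decide. Such a gene must be called in every line, and splits of a line other than the real one gave at most 1 call. The interaction gave 4435 genes (highest other 989, 1 split). The splits exchange treated and untreated labels, so they test for any effect of treatment, not for an equal response of the lines. Chance is therefore not excluded by them for the interaction. Nor is it excluded by them for the genes in which a line differed from the others: Nalm6 561 (highest other 112, 1 split), SUPB15 669 (898, 2 splits), RS411 234 (59, 1 split), REH 504 (1018, 2 splits), 697 1991 (607, 1 split), CEM 244 (697, 2 splits) and DND41 1275 (1651, 3 splits). The real split is included in each number. Each line's split was drawn from all 10, the real one among them, so a draw could keep the real labels of some lines. The highest other values are therefore not free of treatment effects. In SUPB15, REH, CEM and DND41 another draw gave more genes than the real split, and which lines kept their labels there was not examined. For the number of gene lists called in the mean response, 11, chance cannot be excluded, since 29 of 100 splits called as many and the highest other called 14.

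Within a line the 6 libraries have 10 splits, too few for a share under 0.05. The real split gave 3152 genes in Nalm6, 4001 in SUPB15, 401 in 697, 5974 in CEM and 4073 in DND41, where the highest other gave 0, and 2171 in RS411 and 4224 in REH, where the highest other gave 1. In SUPB15, RS411, REH, CEM and DND41, whose replicates were paired, the other splits that part 3 pairs also gave 0 genes. For gene lists the real split gave 10, 10, 11, 12, 13, 10 and 12 in Nalm6, SUPB15, RS411, REH, 697, CEM and DND41, and the highest other 10, 8, 8, 12, 11, 11 and 11. As many lists came from 3, 1, 1, 2, 1, 2 and 1 splits in the same order, and among splits that part 3 pairs of the paired lines the highest were 8, 8, 12, 8 and 10.

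The first untreated libraries of Nalm6, SUPB15, RS411, 697 and DND41 deviated alike, with SNORD3A, TMEM160 (-3.33), SCARNA2 (-2.83), S1PR4 (-2.45) and ALKBH7 (-2.37) low and PTMAP2 (1.5), PTMAP4 (1.30), NSRP1 (1.27), PRRC2C (1.26) and EEF1A1P9 (1.23) high. The deviations correlated at 0.71, and still at 0.70 once trends with GC content and length were removed, which argues against such trends as the whole cause. Low depth is argued against by the first untreated libraries of REH and CEM, the shallowest of the 7, whose deviations had a median correlation of 0.19 with those of the 5. Handling of RNA or library preparation on a shared day stays open, since no label gives a date, and no biological explanation was tested. A result that involves the low genes of these libraries, such as the rise of SNORD3A in Nalm6, may owe part of its size to them. They also had the lowest share of 6 abundant small noncoding RNAs in their groups (3.35% to 7.23%), and the mean of that share was higher after treatment in 6 of the 7 lines, so a different composition of the libraries stays open for transcripts that lack a poly(A) tail, though the histone list did not rise in Nalm6, where the share did, and rose in DND41, where the share did not. Whether the listed histone transcripts lack such a tail was not examined.

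ASNS rose in REH, 697 and CEM and did not pass in Nalm6, SUPB15, RS411 and DND41. In SUPB15 and RS411, too few ASNS counts are argued against as the reason that no rise as large as the other 3 was seen. The upper 95% bounds of the log2 fold change there, 0.86 and 0.53, lie below the lower 95% bound of the smallest of the 3 rises, 1.07 in REH. A smaller rise missed for lack of counts stays open in both. Too few counts are argued against in Nalm6 by its counts, at least 1786 per library, where the untreated libraries of CEM had at most 568. Its upper bound of 1.11 also exceeds 1.07, however, so a rise of that size is not excluded. For DND41, with 57 to 153 ASNS counts per library, the upper bound of 1.28 exceeds 1.07, so too few counts stay open there. The pattern rests on few libraries, as ASNS in Nalm6 passed without untreated B (1.0) and ASNS in DND41 without L-asparaginase A (0.84). A weaker stress response may account for Nalm6 and DND41, where the 19 stress response regulators had medians of 0.45 and 0.59 in the joint model. The highest joint-model median among the 4 lines was 1.36, in SUPB15, as high as in 697 and above REH (1.12) and CEM (1.13). For RS411 the 2 medians differ. Its median was 1.05 over 19 regulators in the joint model, but 1.36 over 18 in its own model. The own models gave 1.30 in 697 and 1.16 in REH, each over 18, and 1.14 in CEM over 17. The sets of genes thus differ as well as the models, and which of these moved the median was not tested. Whether the stress response sets the rise of ASNS therefore stays open for Nalm6, RS411 and DND41, and so do differences in the ASNS gene itself, which these counts do not show.

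Transcripts of other cells stood out in 3 treated libraries. For SUPB15 C, another of the 7 lines is argued against as the only source, since 59 of its 89 genes were higher there than in any other line. A part from another line stays open, as this library held 23.3% (RS411) to 40.8% (697) of the genes abundant in another line and lacking in the other SUPB15 libraries, which may also be genes of other cells. RNA of brain cells is a candidate source: of 11 brain markers lacking in the other SUPB15 libraries, 8 (72.7%) had at least 3 counts, with SYN1 at 1.99 CPM, VSNL1 at 1.52 and STMN2 at 1.39, beside SNAP25 at 25.6, against 0 of 16 liver, 1 of 10 skeletal muscle and 0 of 14 gut markers, though MOBP and MOG had none and GFAP 1 count, so the kind of cell stays open. For REH A, RNA of RS411 cells is a candidate source, since 40 of 40 genes abundant in RS411 and lacking in the other REH libraries (100%) were seen there, at a median of 1.38% of their RS411 level. RS411 B had 59 of 73 such genes of CEM (80.8%) at a median of 0.147%, which may be a trace of CEM, though 58.3% of those of DND41 were seen too. Lesser traces were not confined to these 3 libraries. Untreated 1 of 697 had 8 of 36 such genes of SUPB15 (22.2%), at a median of 0.0255%. L-asparaginase B of REH had 9 of 53 such genes of DND41 (17.0%).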

How the results depend on the processing

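Tests chosen only after the result was seen were the trended dispersion, the removal of GC and length trends, alone or with the replicate block, and the models without the 5 untreated libraries that stood apart or without the 3 treated libraries with transcripts of other cells; the other alternatives were planned. Of 238 named results, 188 kept their direction and their side of the threshold in every alternative run for them. With DESeq2 size factors and with the trended dispersion all 238 did, with DESeq2 4 gained and 1 lost the call, and without the 5 libraries none of 103 mean responses changed its call or direction, while in the 5 lines concerned 89 named results kept theirs and 6 gained the call. Counts of genes stayed within 1.5 times their value, the measure used here, with DESeq2 size factors, without a filter on low counts, with the trended dispersion and without any 1 line, wherever these were run.

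With the replicate block the genes changed were 4100 in SUPB15, 2850 in RS411, 6648 in REH, 6871 in CEM and 6065 in DND41. They were 27 in 697, whose replicates were not paired, and 6 for the same direction in all lines. Called lists were 9 in RS411 and 12 in CEM with the block, in place of 11 and 10. With GC and length trends removed 697 had 1426 genes. With both, RS411 had 3511, REH 6449 and 697 844, and the interaction 6957. DESeq2 called 1659 genes in 697 and 136 with the same direction in all lines. The joint model of 14 groups, which shares 1 dispersion per gene between lines, gave 4170 genes in 697, 2965 in CEM and 168 with the same direction in all lines. Adjusted p-values under 0.01 and 0.1 gave 5 and 114 of the latter. Counts summed per line and compared in pairs gave 4979 genes changed on average, from fewer samples. Except where the construction of the model shows it, the cause was not tested.

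Without the 5 untreated libraries that stood apart, 301 genes had the same direction in all lines and 7549 differed between lines. The genes in which a line differed from the others became 1569 (Nalm6), 1589 (SUPB15), 1093 (RS411), 1274 (REH), 756 (CEM) and 2560 (DND41). Without the 3 treated libraries they became 291 (SUPB15), 77 (RS411) and 298 (REH), with fewer samples. With the replicate block they became 887 (Nalm6), 1078 (SUPB15), 498 (RS411), 849 (REH) and 443 (CEM). With an estimated correlation camera called 2 lists in the mean response and 0 in each of the 7 lines. The cause was not tested.

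Leaving out each library in turn gave 1703 to 3800 genes in Nalm6, 1769 to 6445 in SUPB15, 392 to 4640 in RS411, 2468 to 4588 in REH, 11 to 3751 in 697, 4476 to 6788 in CEM and 1901 to 5397 in DND41. The highest of these values came without the untreated library that stood apart in Nalm6, SUPB15, RS411, 697 and DND41. It gave 2 to 178 with the same direction in all lines, 7528 to 8180 on average and 3798 to 5560 in the interaction. Against the other lines it gave 252 to 1011 in Nalm6, 333 to 1208 in SUPB15, 72 to 582 in RS411, 238 to 754 in REH, 1078 to 2906 in 697, 95 to 427 in CEM and 691 to 1801 in DND41, and the highest of these came without 697 untreated 1 in every line but 697. Called lists ranged from 11 to 13 in the mean response, and the correlation of the untreated level of ASNS with its response from 0.55 to 0.72.

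The depth leaves few counts for weak genes: ASNS in DND41 had 57 to 153 counts per library and a 95% interval of the log2 fold change from -0.21 to 1.28. In simulated data with 3 libraries per group, changes of 1.5-fold were found in 4.5% to 55.4% of genes per line, the lowest share in 697, the line with the largest spread between replicates (a biological coefficient of variation of 0.293, against 0.105 in CEM).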

Other observations

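The tests of hypoxia-induced genes and of snoRNA host genes were chosen only after the result was seen, and the lineage markers below were singled out after their values were seen from lists fixed earlier.

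Several genes of lymphoid identity changed within 4 h of L-asparaginase (± SE of the log2 fold change, SD of CPM, n = 3 per group). The adaptor of the pre-B-cell receptor, BLNK, fell in all 5 B-lineage lines, by -0.72 ± 0.12 in Nalm6, -0.93 ± 0.17 in SUPB15, -0.91 ± 0.17 in RS411, -1.59 ± 0.24 in REH and -2.05 ± 0.32 in 697, where it went from 95.3 ± 38.8 to 23 ± 4.45 CPM. MS4A1, which encodes CD20, rose in Nalm6 (3.76 ± 0.39, adjusted p = 0.00036) and 697 (2.50 ± 0.43, 0.032), from 4.16 ± 2.27 to 23.6 ± 1.82 CPM in the latter. The regulator PAX5 rose in SUPB15 (0.85 ± 0.12), RS411 (0.49 ± 0.12) and REH (0.41 ± 0.10), and EBF1 fell in Nalm6 (-0.72 ± 0.11). The recombinase gene RAG1 fell in both T-lineage lines, in DND41 from 1480 ± 250 to 406 ± 140 CPM (-1.87 ± 0.25, adjusted p = 0.0013) and in CEM from 283 ± 2.86 to 157 ± 9.7 CPM (-0.85 ± 0.081). In DND41 the T-cell receptor subunits CD3D (-0.79 ± 0.13) and CD3G (-0.74 ± 0.14) fell too.

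Outside the lymphoid markers, the myeloid receptor CSF1R rose in SUPB15 (1.24 ± 0.23), RS411 (1.22 ± 0.22) and REH (1.5 ± 0.15, from 4.72 ± 0.385 to 13.3 ± 1.15 CPM). Of the same list, CEBPA fell in RS411 (-1.05 ± 0.24, adjusted p = 0.024) and CEM (-1.02 ± 0.32), and ITGAM fell in CEM (-1.38 ± 0.27). The collagen gene COL6A3, at 925 ± 69.5 CPM in untreated SUPB15, fell to 416 ± 106 CPM (-1.15 ± 0.19), and PDGFRB rose there from 5.86 ± 0.636 to 22.4 ± 1.47 CPM (1.93 ± 0.15, adjusted p = 0.00023). PDGFRA fell in Nalm6 from 324 ± 114 to 158 ± 18.1 CPM (-1.04 ± 0.23), while PDGFRB (0.96 ± 0.18) and TAGLN (1.13 ± 0.32) of the same list rose there.

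With the replicate block, calls of some stress genes changed in paired lines. PHGDH in SUPB15 had an adjusted p of 0.048 in place of 0.11, MYC in REH 0.0072 in place of 0.18, ATF4 in REH 0.02 in place of 0.19 and DDIT4 in DND41 0.026 in place of 0.39, and ATF4 in SUPB15 lost its call (0.057 in place of 0.041).

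Genes induced by hypoxia were among the largest falls, and so a list of them was looked at. Of 27 measured, 17 fell and 3 rose in the mean response, with a median of -0.57. The list holds falls that prompted it, so camera was run without the 6 genes named for other results, among them PFKFB4, P4HA1 and MIR210HG. The other 21 had a median of -0.47 (p = 0.0078, 0.33 with an estimated correlation), and the 13 of these outside the glycolysis list one of -0.36 (0.53, 0.77 with an estimated correlation), so a fall beyond that of glycolysis genes was not shown. Of the 13, 5 were called lower and 2 higher. ADM, CA9, EGLN3, P4HA2 and ANGPTL4 among them had SEs of 840 to 5600, so their estimates were not usable, yet they enter these medians and tests. The median of the 27 was -0.60 without the 5 untreated libraries and -0.56 with GC and length trends removed, and it was below 0 in all 7 lines, but that of the 13 genes was below 0 in 4 lines and above 0 in 2. MIR210HG (-4.06 ± 0.46), AK4 (-1.68 ± 0.32), BNIP3L (-1.46 ± 0.12) and PDK1 (-0.75 ± 0.081) fell, and VEGFA (0.78), VLDLR (1.07) and DDIT4 (1.20) rose. The list shares 9 genes with the glycolysis list and 2 with the stress response regulators. The fall may follow from the size of the stress response, but over the 7 lines the median of 25 list genes outside the stress list and that of the stress regulators had r = -0.05 (exact permutation p = 0.91, BH adjusted 0.91) and rho = -0.36 (exact permutation p = 0.44, BH adjusted 0.89), with r = 0.47 without Nalm6 and DND41, so the cause stays open. Less oxygen use or a different density of the treated cultures was not measured.

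Noncoding host genes of small nucleolar RNAs, whose spliced transcripts are degraded when they are translated, would rise where translation drops. Of 13 such genes 10 rose and 1, SNHG16 (-0.30 ± 0.069), fell, with a median of 0.28 (camera p = 3.4e-05, 0.059 with an estimated correlation), 0.25 without the 5 untreated libraries and a median above 0 in all 7 lines. SNHG1 rose most (0.98 ± 0.056), then SNHG7 (0.70 ± 0.11), SNHG15 (0.61 ± 0.094) and ZFAS1 (0.59 ± 0.066), and GAS5 rose by 0.28 ± 0.046. This is consistent with reduced translation after asparagine loss as a hypothesis, though a change in transcription of these genes was not tested apart from it.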
